A study of Homo sapiens with 24 samples.

How the data were processed

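Mononuclear cells were isolated from blood on a density gradient, frozen, thawed and loaded on a 10x Genomics Chromium instrument with the 3′ v3 chemistry, per the labels' protocols. This chemistry reads the 3′ end of transcripts and tags each captured molecule with a UMI, so that PCR copies are counted once. Cell Ranger, STAR and Seurat 3.2.2 were used with the GRCh38 (hg38) genome, per the submitters' processing notes. The version of Cell Ranger, the annotation and the filters on cells are not given in the sources used here. The deposited matrices hold raw UMI counts for 33694 genes per cell, as whole numbers, for each of the 24 libraries. The deposited cell table gives, per the file headers, each cell's library, batch, cluster number, total UMI count and the percent of UMIs from mitochondrial genes, computed by the authors. Of the 193760 barcodes in the matrices, 191814 are listed in that table and were used. The 1946 others, with 0.385% of the UMIs, were left out. The listed total count equalled the sum over the matrix exactly in 98.5% of cells, and 0 matrices were identical to another. XIST, TSIX and the genes of the Y chromosome (134 in all) were removed before any test.

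The cell table gives 39 cluster numbers over all libraries and no cell type names, so the clusters were named from marker lists fixed before the data were examined. A cluster took the class whose markers had the highest mean log2 fold over the other clusters (pseudocount of 10 CPM). That mean had to reach 0.75, and at least 3 markers had to be detected in 10% of the cells. CD4 T and CD8 T clusters were told apart by a 2-fold ratio between the shares of cells with CD8 and CD4 transcripts. Clusters in which over 50% of cells carried markers of 2 lineages were set apart as mixed, as was 1 cluster with erythroid and monocyte markers. A cluster led by cell cycle genes was called cycling, and clusters without a clear class stayed unnamed. These thresholds were set after the data were seen, and they kept 9.19% of cells before and 9.16% after in unnamed clusters. In the 8 classes compared, every cluster had at least as many markers of its own class as of any other among its top 10 genes. Both counts were 0 in the CD14 monocyte clusters led by EGR1, by HLA-DRB5 and by IFI44L, and in the CD4 T cluster led by RTKN2. There the check gave the names no support. No doublet caller was run. A cell counted as carrying markers of 2 lineages when it had at least 2 UMIs of the markers of each of 2 lineages (T, B, myeloid or platelet). Such cells, which can be doublets or hold RNA of other cells, made up 16.3% of all cells (5.08% to 28.4% per library) and were left out in an alternative. Their share was unequal between classes. It was 41.8% in the CD16 monocyte cluster and 31.4% in the larger conventional dendritic cluster, against 4.47% to 8.24% in the CD4 T clusters.

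The share of each class among all cells was compared as log2 odds (0.5 added to each count), after minus before per patient. The test was a two-sided sign-flip permutation test that enumerated all 4096 sign patterns of 12 patients. For genes, UMI counts were summed per library and class, since cells are not replicates. Patients with at least 10 cells of the class in both samples entered the fit, which were 9 for plasmacytoid dendritic cells, 11 for CD16 monocytes and 12 for the 6 other classes. edgeR 4.0.16 (R 4.3.3) was run with TMM factors, filterByExpr, robust dispersions and the quasi-likelihood F test with patient as a block. P-values were adjusted by the Benjamini-Hochberg method within each class at a threshold of 0.05. The summed counts per library ranged from 42892 to 674971 UMIs in plasmacytoid dendritic cells, 143798 to 1381566 in conventional dendritic cells and 60828 to 23398749 in CD14 monocytes. They ranged from 386714 to 4360105 in CD16 monocytes, 383541 to 8166177 in NK cells and 233729 to 9924530 in CD8 T cells. In CD4 T cells the range was 1668593 to 16221643 UMIs and in B cells 85443 to 1513405.

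The pairing came from the labels, which give the same patients at both time points. The deviations of a patient's 2 samples from their group means correlated with a median r between 0.209 in plasmacytoid dendritic cells and 0.642 in CD8 T cells. The correlation was over 0.1 in every pair of the other 7 classes and in 8 of the 9 pairs of plasmacytoid dendritic cells.

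The 23 gene lists were also fixed in advance. A list with at least 5 tested members was scored per library as the mean log2 CPM (edgeR, prior count 2). The score was compared after minus before with the two-sided sign-flip test, adjusted over all 135 combinations of class and list. The smallest p this test can give is 0.00391 with 9 patients, 0.000977 with 11 and 0.000488 with 12. Beside it, camera and fry (limma 3.58.1) were run in the same blocked fit. Camera compares a list with other genes, and fry tests whether the members of a list move, on balance, one way. The change of the interferon list was compared between plasmacytoid dendritic cells and each other class within patients. The rule for named genes took, per class, the 5 genes of smallest p in each direction among those past the threshold that moved the same way in at least 80% of patients. It left out immunoglobulin and T cell receptor variable genes, HLA-DRB3 to HLA-DRB5 and genes with only a clone name. It added up to 4 members of smallest p of each list described for a class, and the cell type markers. No gene passed the threshold, so the named genes came from the lists and markers. Gene positions are those of GENCODE 29 on GRCh38, matched by the gene IDs in the deposited files.

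The gene test was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by a fold that was equal in every patient. Of the genes changed 1.5-fold it called 41.7% in plasmacytoid dendritic cells (2325 genes tested), 74.0% in conventional dendritic cells (5708 genes), 87.8% in CD14 monocytes (10770 genes) and 80.0% in CD16 monocytes (8628 genes). It called 81.2% in NK cells (9362 genes), 76.0% in CD8 T cells (10540 genes), 85.7% in CD4 T cells (9762 genes) and 78.7% in B cells (6829 genes). Unchanged genes made up 2.06% (B cells) to 8.62% (CD8 T cells) of all calls. Changes that vary between patients were not simulated, so these rates do not give the share of real changes that the test would call. In conventional dendritic cells 95.9% of genes changed 3-fold were called in the simulation. In the real data IFI44L had a fitted fold of 3.40 there and an edgeR adjusted p of 0.844. A simulated effect of 1 SD in 12 patients gave a sign-flip p under 0.05 in 85.0% of 300 sets, and no effect did so in 3.67%.

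Alternatives set in advance for genes were DESeq2 size factors in edgeR, no filter beyond 1 count, DESeq2's Wald test (version 1.42.0), no patient block, at least 50 cells per sample, no cells with markers of 2 lineages, and leaving out each patient in turn. For shares they included percentage points and another denominator, for lists a prior count of 0.5, and for the interferon comparisons of plasmacytoid dendritic cells thinning of the other class to the same summed UMI count (10 draws), which left the number of list members tested unequal. Added after the data were seen were batch 3 alone, the 50-cell and 2-lineage settings for lists and interferon comparisons, and CD14 monocytes without 1 cluster. The comparison of conventional dendritic cells with lymphocytes and the comparison over shared list members were added then as well. The matrix that pools the whole series was not used here.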

Results

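The study asked how circulating immune cells differ before and during treatment of glioblastoma, a malignant brain tumour, with tumour treating fields (TTFields), alternating electric fields applied to the head, given together with the alkylating drug temozolomide (TMZ). Blood mononuclear cells of 12 patients were profiled by droplet-based single-cell RNA sequencing, which counts unique molecular identifiers (UMIs) per gene and cell. All patients had completed chemoradiation for a new diagnosis. Each gave 1 sample shortly before the start of TTFields with TMZ (before) and 1 sample about 4 weeks later (after), so that the 24 libraries formed 12 pairs. No group without TTFields was analysed here, so a difference between after and before holds the effects of TTFields, TMZ and time together. The libraries held 4812 to 12849 cells and 13032152 to 62818405 UMIs, with a median of 30372786.5 UMIs. The median UMIs per cell ranged from 1866 to 6653, and the median mitochondrial share of a cell's UMIs from 6.06% to 18.3%. The 3 deposited batches held 2, 2 and 8 patients, both samples of a patient lay in the same batch. The 4 libraries of batch 1 were the deepest, at a mean of 5725 ± 1002 median UMIs per cell (SD) against 2229 ± 405 in the 4 libraries of batch 2 and 2804 ± 518 in the 16 libraries of batch 3.

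The 191814 cells fell into 39 deposited clusters without cell type names, and the clusters were named from marker genes fixed before the data were examined, so that each name below stands for cells that resemble that type. Plasmacytoid dendritic cells, the main producers of type I interferon in blood, formed 1 cluster of 642 cells led by LILRA4, PLD4 and TCF4. Conventional dendritic cells, which present antigen to T cells, comprised 1705 cells in 2 clusters, the larger led by FCER1A, CLEC10A and CD1C. CD14 monocytes made up 41229 cells in 5 clusters. Of these, 1 was led by the immediate early genes EGR1 and FOSB and drew 54.9% of its cells from a single library, 1 was led by the interferon-induced genes IFI44L, IFIT1 and MX1, and 1 drew 76.5% of its 4557 cells from a single library. CD16 monocytes (7484 cells, led by CDKN1C and LYPD2) and B cells (6357 cells, led by MS4A1 and CD79A) formed 1 cluster each. NK cells comprised 30142 cells in 4 clusters, of which 1 drew 46.9% of its cells from a single library, and CD8 T cells 41801 cells in 5 clusters. CD4 T cells comprised 30041 cells in 3 clusters, led by TSHZ2 and CCR7, by IL7R and LTB, and by RTKN2 and FOXP3, the transcription factor of regulatory T cells. Plasma cells, platelets, erythroid cells, progenitors and cycling cells formed 1 cluster each, 5 clusters of mixed lineage were set apart, and 7 clusters stayed unnamed. The unnamed clusters took 9.19% ± 7.84 of the cells before and 9.16% ± 9.68 after (SD, n = 12). They included 1 cluster led by FABP4, CCL2 and CXCL8 with 4314 of its 4317 cells in batch 1.

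The first comparison asked whether the makeup of the blood sample differed between the time points. Plasmacytoid dendritic cells took 0.281% ± 0.296 of the cells before and 0.406% ± 0.301 after (SD, n = 12), with a higher share after in 9 of 12 patients and a mean log2 odds difference of 0.94 ± 1.25. NK cells, innate cytotoxic lymphocytes, took 12.2% ± 8.71 before and 17.5% ± 11.3 after, again higher in 9 of 12 patients, with a mean log2 odds difference of 0.61 ± 0.90. CD14 monocytes took 25.5% ± 17.1 before and 19.1% ± 13.5 after and were lower in 8 of 12 patients, with a mean log2 odds difference of -0.45 ± 0.95, which ran from -0.58 to -0.29 with 1 patient left out at a time. Conventional dendritic cells took 1.03% ± 0.632 before and 0.857% ± 0.455 after and were lower in 9 of 12 patients, with a mean log2 odds difference of -0.20 ± 1.05 (permutation p = 0.512, adjusted p = 0.809). That mean ran from -0.40 to -0.05 with 1 patient left out at a time. Erythroid cells took 0.435% ± 0.587 before and 0.168% ± 0.262 after, with a mean log2 odds difference of -1.13 ± 1.73. CD8 T cells were 19.9% ± 9.81 before and 20.8% ± 12.1 after, CD4 T cells 17.3% ± 10.1 and 16.3% ± 9.58, and B cells 3.25% ± 1.41 and 3.25% ± 1.40. None of the 15 shares passed the paired sign-flip permutation test after Benjamini-Hochberg adjustment. The 2 with an unadjusted p under 0.05 were plasmacytoid dendritic cells (p = 0.0269, adjusted p = 0.269) and NK cells (p = 0.0396, adjusted p = 0.269). With 1 patient left out at a time, their permutation p ran up to 0.0537 and 0.0791. On percentage points it was 0.194 and 0.0293 over all patients. On log2 odds over all patients, the values were p = 0.0537 (adjusted p = 0.269) for erythroid cells and p = 0.130 (adjusted p = 0.487) for CD14 monocytes. None of the 39 single clusters passed either, with a smallest p of 0.0117 and an adjusted p of 0.451. Within batch 3 the mean log2 odds differences were 0.59 for plasmacytoid dendritic cells and 0.80 for NK cells (exact sign-flip p = 0.195 and 0.0469, adjusted p = 0.488 and 0.352, n = 8). For conventional dendritic cells it was -0.75 there (exact sign-flip p = 0.00781, the smallest that 8 patients can give, adjusted p = 0.117). Batches 1 and 2 held too few patients to test.

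**Figure D1:**
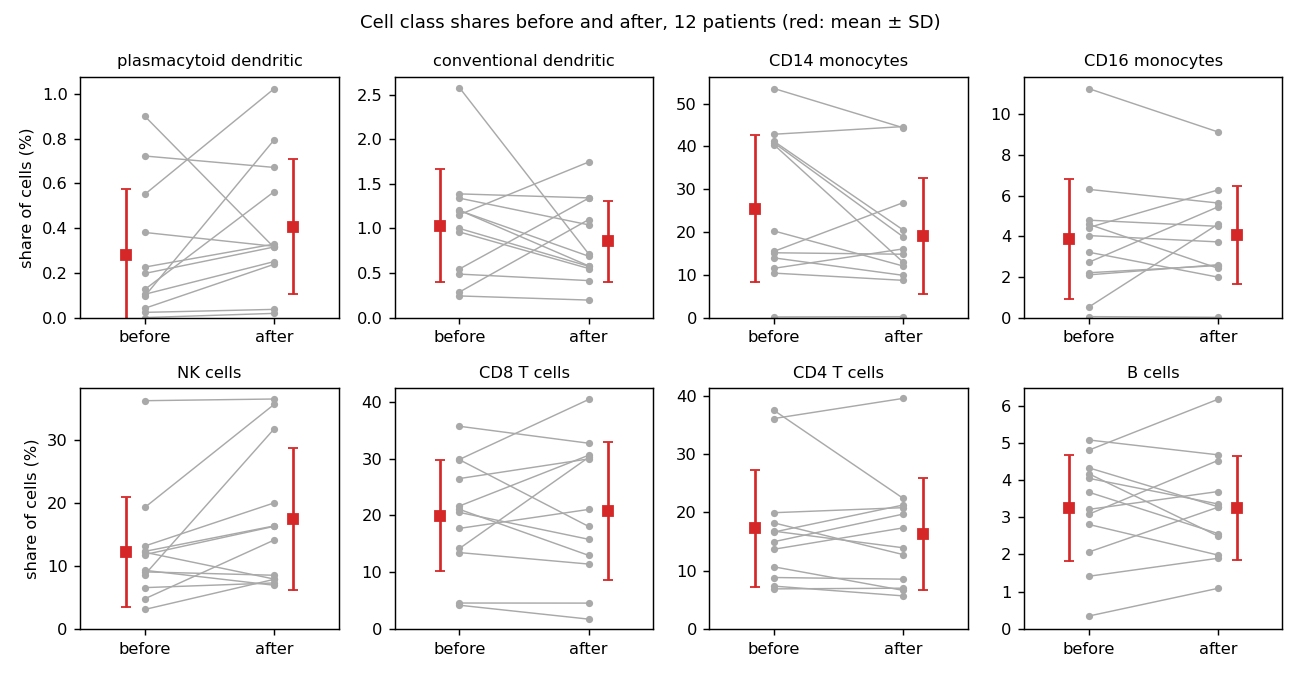
Share of all cells (%, vertical axis) of 8 cell classes before and after the start of TTFields with TMZ. Each grey line joins the 2 samples of 1 of 12 patients and red squares with bars give mean ± SD; plasmacytoid dendritic cells and NK cells were higher after in 9 of 12 patients each, and no share passed the adjusted test.

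The second comparison asked which genes and gene groups differed between the time points within each cell class, and the type I interferon genes, the antiviral response genes that interferon induces, are given first. In conventional dendritic cells, all 23 measured members of this list had fitted fold changes above 1. The mean change of the list was 0.49 ± 0.64 log2 units (SD, n = 12), and the list was higher after in 9 of 12 patients. IFI44L went from 13.7 ± 11.7 to 54.9 ± 59.4 CPM (counts scaled to the same total in every library), a log2 fold change of 1.77 ± 0.43 (SE). IRF7, the transcription factor that amplifies interferon production, had a log2 fold change of 0.66 ± 0.15 and was higher after in 11 of 12 patients. IFI44 and OAS3, the latter an enzyme of the antiviral RNA decay pathway, had log2 fold changes of 0.84 ± 0.19 and 0.75 ± 0.21. Of the 23 members, 12 rose and 0 fell when adjusted over the list alone, with adjusted p = 0.00152 for IFI44 and IRF7, 0.00823 for OAS3 and 0.0115 for IFI44L. None passed edgeR's quasi-likelihood test adjusted over all 5880 genes (adjusted p = 0.259 for IFI44 and IRF7). The sign-flip permutation test of the list gave p = 0.0186, and adjusted over all 135 combinations of class and list it did not pass (adjusted p = 0.410). Camera with a preset correlation of 0.01 gave adjusted p = 5e-18, against adjusted p = 0.374 with an estimated correlation. Without cells carrying markers of 2 lineages the mean change was 0.37 ± 0.63 (9 of 12 patients higher, permutation p = 0.0708). The cytotoxic effector list, genes of NK and T cells, had a mean change of 0.52 ± 1.24 in conventional dendritic cells (permutation p = 0.159). IFI44L (gene ID ENSG00000137959) lies on chromosome 1 from 78619922 to 78646145, next to IFI44 (ENSG00000137965) from 78649796 to 78664078, and IRF7 (ENSG00000185507) lies on chromosome 11 from 612553 to 615999 in GRCh38.

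**Figure D2:**
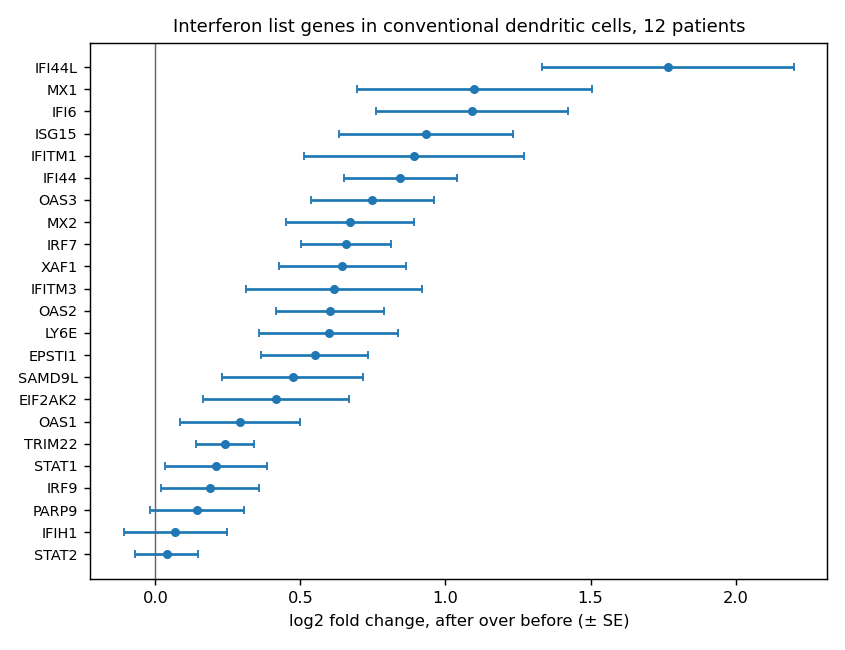
Log2 fold change, after over before (horizontal axis), of the 23 measured type I interferon list genes in conventional dendritic cells of 12 patients, with bars of ± 1 SE. All 23 fitted values lie above 0, the highest being IFI44L at 1.77.

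The other myeloid and dendritic classes had list means of similar size. In CD14 monocytes 31 of 33 members were fitted higher and the mean change was 0.59 ± 0.79 (SD, n = 12; 8 of 12 patients higher; permutation p = 0.0190, adjusted p = 0.410). The smallest CD14 monocyte sample held 13 cells and the largest 5090, and each patient had the same weight in this mean. With each patient left out in turn, the mean ran from 0.44 to 0.67 (permutation p up to 0.0381). MX1, an antiviral GTPase, had a log2 fold change of 1.11 ± 0.33 there, HERC5, the ligase of the ubiquitin-like protein ISG15, 1.03 ± 0.33, and IRF7 0.54 ± 0.15. Of the 33 members 0 passed when adjusted over the list alone (adjusted p = 0.0636 for each of these 3). Without the interferon-led cluster, a comparison added after the data were seen, the mean was 0.36 (permutation p = 0.0420). The cytotoxic effector list had a mean change of 0.15 ± 0.72 in CD14 monocytes (permutation p = 0.473), with 1 member rising when adjusted over the list alone. In CD16 monocytes 29 of 32 interferon members were fitted higher and the mean change was 0.42 ± 0.64 (SD, n = 11; 7 of 11 patients higher; permutation p = 0.0361, adjusted p = 0.443). Leaving out 1 patient at a time, that mean ran from 0.28 to 0.48 (permutation p up to 0.0723). OASL, with a log2 fold change of 0.77 ± 0.20, rose when adjusted over the list alone (adjusted p = 0.0265). Without cells carrying markers of 2 lineages the mean in CD16 monocytes was 0.38 ± 0.62 (permutation p = 0.0752). In plasmacytoid dendritic cells of the 9 patients with enough cells, all 7 measured members were fitted higher, with a mean change of 0.45 ± 0.65 (7 of 9 patients higher; exact sign-flip p = 0.0703, adjusted p = 0.650, n = 9). Leaving out 1 patient at a time, the mean ran from 0.29 to 0.55. Without cells carrying markers of 2 lineages the mean was 0.27 ± 0.37 (exact sign-flip p = 0.0859, n = 8). LY6E had the smallest p of these 7, with 61.2 ± 41.1 CPM before and 126 ± 52.6 CPM after and a log2 fold change of 1.11 ± 0.36, which did not pass adjusted over the list alone (edgeR adjusted p = 0.0543). Without 1 of the 9 patients its log2 fold change was 1.67, which passed over all genes (edgeR adjusted p = 0.00711). Camera with the preset correlation called the list higher in CD14 monocytes, CD16 monocytes and plasmacytoid dendritic cells (adjusted p = 5e-28, 1.5e-19 and 3.9e-05), and none of these calls held with an estimated correlation (adjusted p = 0.374, 0.429 and 0.533). Within batch 3 the mean change was 0.57 in conventional dendritic cells, 0.55 in CD14 monocytes and 0.46 in CD16 monocytes (exact sign-flip p = 0.0313, 0.0938 and 0.0469, n = 8), and 0.51 in plasmacytoid dendritic cells (exact sign-flip p = 0.125, n = 6). With the gene filter and scaling repeated in batch 3 alone, the mean in plasmacytoid dendritic cells was 0.40 (exact sign-flip p = 0.219, n = 6).

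Lymphocytes had smaller list means. The interferon list had a mean change of 0.24 ± 0.42 in B cells (20 of 22 members fitted higher, 9 of 12 patients higher, permutation p = 0.0698, adjusted p = 0.650). The cytotoxic effector list had a mean change of 0.33 ± 0.92 in B cells (13 of 16 members fitted higher, permutation p = 0.240), which camera called with the preset correlation (adjusted p = 0.00231) and not with an estimated one (adjusted p = 0.826). The mean change was 0.15 ± 0.30 in NK cells (24 of 29 members, 9 of 12 patients, permutation p = 0.120, adjusted p = 0.731). The means were 0.08 ± 0.25 in CD4 T cells (20 of 31 members, 4 of 12 patients, permutation p = 0.349, adjusted p = 0.907) and 0.03 ± 0.28 in CD8 T cells (20 of 32 members, 6 of 12 patients, permutation p = 0.724, adjusted p = 0.949). With 1 patient left out at a time, the means ran from 0.09 to 0.18 in NK cells, 0.03 to 0.11 in CD4 T cells and -0.02 to 0.07 in CD8 T cells. Without cells carrying markers of 2 lineages the mean in CD4 T cells was 0.04. In NK cells MX2 rose when adjusted over the list alone, with a log2 fold change of 0.40 ± 0.11 (adjusted p = 0.0259). In CD4 T cells RSAD2, which makes an antiviral nucleotide, did so with 0.79 ± 0.19 (adjusted p = 0.00545). In B cells IFI44L and HERC5 had log2 fold changes of 1.16 ± 0.39 and 0.62 ± 0.19, and no member passed when adjusted over the list alone (adjusted p = 0.0701 and 0.0532). Camera with the preset correlation called the list higher in B, NK and CD4 T cells (adjusted p = 1.7e-05, 0.000251 and 0.0265), against adjusted p = 0.649, 0.826 and 0.826 with an estimated correlation. It did not call the list in CD8 T cells (adjusted p = 0.0567).

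**Figure D3:**
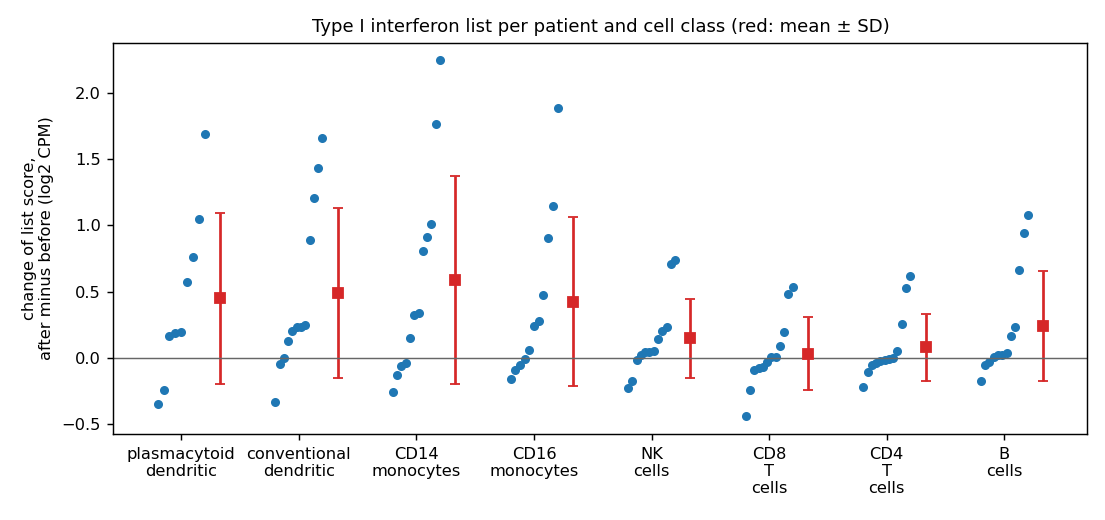
Change of the type I interferon list score, after minus before in log2 CPM (vertical axis), in 8 cell classes. Blue points are patients (9 for plasmacytoid dendritic cells, 11 for CD16 monocytes, 12 elsewhere) and red squares with bars give mean ± SD, from 0.59 ± 0.79 in CD14 monocytes to 0.03 ± 0.28 in CD8 T cells.

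Whether the interferon change in plasmacytoid dendritic cells differed from that in each other class was tested within the 9 patients who had both values. The mean difference from CD4 T cells was 0.34 ± 0.40 (exact sign-flip p = 0.0391, adjusted p = 0.137, n = 9). From CD8 T cells it was 0.36 ± 0.45 (exact p = 0.0547, adjusted p = 0.137) and from NK cells 0.28 ± 0.39 (exact p = 0.0586, adjusted p = 0.137). Each was higher in plasmacytoid dendritic cells in 7 of 9 patients. The mean differences from B cells, conventional dendritic cells, CD14 monocytes and CD16 monocytes were 0.14, 0.02, -0.10 and 0.01 (exact p = 0.383, 0.781, 0.469 and 0.941). None of the 7 differences passed the adjusted test. These scores covered 7 list members in plasmacytoid dendritic cells and 22 to 33 in the other classes. Over the 7 shared members the differences were 0.35, 0.40 and 0.24 from CD4 T, CD8 T and NK cells. They were 0.11, 0.12, 0.04 and 0.13 from B cells, conventional dendritic cells, CD14 monocytes and CD16 monocytes. None of these passed either (smallest exact sign-flip adjusted p = 0.137, n = 9).

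Genes of MHC class II presentation, which display peptides to CD4 T cells, had lower values after treatment in CD4 T cells and CD16 monocytes. In CD4 T cells all 9 measured members were fitted lower, the mean change was -0.30 ± 0.33 log2 units (SD, n = 12), and the list was lower in 11 of 12 patients. HLA-DRA, the alpha chain of HLA-DR, went from 51.4 ± 28.6 to 36.4 ± 17.1 CPM, a log2 fold change of -0.50 ± 0.11, and HLA-DMB, HLA-DRB1 and HLA-DQA1 had log2 fold changes of -0.56 ± 0.16, -0.55 ± 0.14 and -0.56 ± 0.17. Of the 9 members 6 fell when adjusted over the list alone (adjusted p = 0.00219 for HLA-DRA), while 0 passed over all 9808 genes tested by edgeR (adjusted p = 0.361 for HLA-DRA). The list test gave a permutation p of 0.0132 and an adjusted p of 0.410, and camera gave an adjusted p of 8.7e-12 with the preset correlation and adjusted p = 0.374 with an estimated correlation. In batch 3 all 8 patients had a lower list value (mean -0.34 ± 0.23, exact sign-flip p = 0.00781, n = 8). There edgeR called HLA-DRA and HLA-DRB1 lower over all genes (log2 fold changes of -0.46 and -0.50, adjusted p = 0.0291 and 0.0352). Without 1 of the 12 patients HLA-DRA was also called (log2 fold change -0.59, adjusted p = 6.5e-05). In CD16 monocytes all 11 members were fitted lower, with a mean of -0.23 ± 0.32 (SD, n = 11; 9 of 11 patients lower; permutation p = 0.0244, adjusted p = 0.410). Of the 11 members 5 fell when adjusted over the list alone, among them HLA-DPB1 at -0.20 ± 0.07 and HLA-DQA1 at -0.37 ± 0.12 (adjusted p = 0.0271 each). Camera gave an adjusted p of 1.1e-11 there, against adjusted p = 0.374 with an estimated correlation, and the mean within batch 3 was -0.18 (exact sign-flip p = 0.164, n = 8). In conventional dendritic cells and B cells the list means were 0.14 ± 0.27 and 0.10 ± 0.20 (permutation p = 0.0962 and 0.101, adjusted p = 0.650 each), and in CD8 T cells -0.14 ± 0.25 (permutation p = 0.0791, adjusted p = 0.650). Camera with the preset correlation called the list higher in conventional dendritic cells and B cells and lower in CD8 T cells (adjusted p = 1.7e-05, 0.000484 and 0.00211), against adjusted p = 0.603, 0.649 and 0.649 with an estimated correlation. The means were 0.02 in NK cells, 0.01 in CD14 monocytes and -0.005 in plasmacytoid dendritic cells. Monocyte transcripts were also seen in CD4 T cells, where LYZ, a monocyte gene, had 63.3 ± 41.4 CPM before and 48.4 ± 28.7 CPM after. Its log2 fold change was -0.28 ± 0.13 and that of S100A8 -0.34 ± 0.18 (edgeR adjusted p = 0.971 and 0.980). The HLA genes of the list lie in the class II region of chromosome 6, HLA-DRA (ENSG00000204287) from 32439842 to 32445046 and HLA-DQA1 from 32628179 to 32647062 in GRCh38. Their close relation and many alleles make the split of UMIs between class II genes uncertain.

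Cytotoxic and ribosomal protein genes in CD4 T cells, and p53 target genes in CD4 and CD8 T cells, had list tests with an unadjusted p under 0.05 that did not pass after adjustment. In CD8 T cells the cytotoxic and ribosomal means were 0.02 ± 0.30 and 0.08 ± 0.26 (permutation p = 0.832 and 0.318). In CD4 T cells 14 of 16 cytotoxic effector genes were fitted lower and the mean change was -0.20 ± 0.27 (SD, n = 12; 8 of 12 patients lower; permutation p = 0.0264, adjusted p = 0.410). GZMA, which encodes granzyme A, and CST7 fell when adjusted over the list alone, with log2 fold changes of -0.58 ± 0.14 and -0.25 ± 0.08 (adjusted p = 0.0166 each), and PRF1, the pore-forming perforin, had -0.23 ± 0.09 (adjusted p = 0.0678). Without cells carrying markers of 2 lineages the cytotoxic mean was -0.17 ± 0.30 (permutation p = 0.0811), and with the fit repeated in batch 3 it was -0.09 ± 0.21 (exact sign-flip p = 0.273, n = 8). All 20 ribosomal protein genes were fitted higher in CD4 T cells, with a mean of 0.12 ± 0.17 (9 of 12 patients higher, permutation p = 0.0264, adjusted p = 0.410). RPS27 went from 11225 ± 2809 to 12883 ± 2446 CPM, a log2 fold change of 0.22 ± 0.06, and was the 1 member that rose when adjusted over the list alone (adjusted p = 0.0338). Ribosomal protein genes have many processed pseudogenes, so their counts carry that uncertainty. The p53 target list, genes induced by DNA damage, had means of -0.09 ± 0.10 in CD8 T cells (9 of 12 patients lower, permutation p = 0.0112) and -0.07 ± 0.08 in CD4 T cells (10 of 12 patients lower, permutation p = 0.0156), with an adjusted p of 0.410 for both. TNFRSF10B, a death receptor, fell in CD8 T cells when adjusted over the list alone (log2 fold change -0.56 ± 0.17, adjusted p = 0.0495). MDM2, which marks p53 for degradation, had -0.15 ± 0.07 there (adjusted p = 0.290) and FAS -0.21 ± 0.08 in CD4 T cells (adjusted p = 0.217). Camera with the preset correlation called the cytotoxic, ribosomal and p53 lists in CD4 T cells and the p53 list in CD8 T cells (adjusted p = 3e-05, 1.1e-11, 0.0302 and 0.0181), against adjusted p = 0.374, 0.429, 0.374 and 0.573 with an estimated correlation. With the fit repeated in batch 3 the p53 mean was -0.07 in CD8 T cells and -0.06 in CD4 T cells (exact sign-flip p = 0.0469 each, n = 8), and the ribosomal mean in CD4 T cells was 0.12 (exact p = 0.0859).

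Immediate early genes, which respond within minutes to stimulation, had list means above 0 in all 8 classes, from 0.09 to 0.24, of which 1 had an unadjusted p under 0.05. In NK cells 11 of 13 members were fitted higher with a mean of 0.24 ± 0.32 (SD, n = 12; 9 of 12 patients higher; permutation p = 0.0273, adjusted p = 0.410). NR4A2, an orphan nuclear receptor, rose when adjusted over the list alone (log2 fold change 0.86 ± 0.22, adjusted p = 0.00949), and the AP-1 subunits FOS and JUNB had 0.46 ± 0.16 and 0.43 ± 0.18 (adjusted p = 0.0704 and 0.110). In conventional dendritic cells all 8 measured NF-kB and inflammatory cytokine genes were fitted higher, with a mean of 0.21 ± 0.31 (10 of 12 patients higher, permutation p = 0.0322, adjusted p = 0.435). NFKBIZ had 0.40 ± 0.19 and IL1B, which encodes interleukin-1 beta, 0.47 ± 0.31, and no member passed when adjusted over the list alone (adjusted p = 0.293 for both). Camera with the preset correlation called both lists higher (adjusted p = 0.000998 and 0.0183), against adjusted p = 0.374 for both with an estimated correlation. With the fit repeated in batch 3 the means were 0.26 for each list (exact sign-flip p = 0.0391 and 0.0703, n = 8).

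The remaining lists gave no unadjusted p under 0.05 in any class. Cytosolic DNA sensing and inflammasome genes had list means between -0.08 and 0.19 (smallest permutation p = 0.372, in NK cells) and heat shock genes between -0.21 and 0.06 (p = 0.377, CD14 monocytes). Glucocorticoid response genes had means between -0.25 and 0.19 (exact p = 0.359, plasmacytoid dendritic cells) and suppressive monocyte genes between -0.33 and 0.16 (p = 0.250, CD8 T cells). The glucocorticoid changes of single patients were large in both directions. They were 0.17 ± 1.30 (SD) in CD14 monocytes, from -2.41 to 1.87, and 0.03 ± 1.32 in CD16 monocytes, from -2.43 to 1.87. The CD14 monocyte cluster with 76.5% of its cells from 1 library had IL1R2, ZBTB16 and FKBP5 of this list among its top genes. MHC class I presentation genes had means between -0.02 and 0.16 (p = 0.0903, B cells) and dendritic cell maturation genes between -0.19 and 0.02 in 3 classes (p = 0.0869, CD16 monocytes). Checkpoint and exhaustion genes had means below 0 in all 3 classes where they were measured, the lowest being -0.21 ± 0.41 in CD8 T cells (p = 0.0791). T cell activation genes had means between -0.13 and 0.05 (p = 0.157, NK cells), naive and central memory T genes a highest mean of 0.19 in CD14 monocytes (p = 0.219), and cell cycle genes a lowest mean of -0.13 in CD8 T cells (p = 0.253). Mitochondrially encoded genes had means between -0.13 and 0.06 (exact p = 0.227, plasmacytoid dendritic cells), platelet markers between -0.08 and 0.36 (p = 0.524, CD4 T cells), and plasma cell markers 0.09 in B cells (p = 0.301). Erythroid, neutrophil and progenitor markers had under 5 measured members in every class and were not tested. The adjusted p of each of these was 0.650 or more. Over all 135 combinations 11 had an unadjusted p under 0.05, where 6.75 are expected by chance, and 0 passed after adjustment. The smallest sign-flip p with 12 patients, 0.000488, would not pass over 135 tests if 1 list alone reached it. The count of 0 thus does not show that no list changed. Camera called 34 with the preset correlation (22 higher, 12 lower) and 0 with an estimated one, and fry called 0 (smallest adjusted p = 0.537). The mean list change and the median fitted fold change of the members differed in sign in 17 of the 135 combinations, none of them among the 34.

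No single gene passed edgeR's quasi-likelihood test with patient as a block after adjustment over all genes of a class, in any of the 8 classes. The numbers of genes with an unadjusted p under 0.05 were 61 of 2476 tested in plasmacytoid dendritic cells, 282 of 5880 in conventional dendritic cells, 361 of 10868 in CD14 monocytes and 332 of 8766 in CD16 monocytes. They were 442 of 9455 in NK cells, 570 of 10654 in CD8 T cells, 489 of 9808 in CD4 T cells and 311 of 7012 in B cells. Chance alone gives 124, 294, 543, 438, 473, 533, 490 and 351. DESeq2's Wald test called 1 gene, in conventional dendritic cells, and 0 in the other 7 classes. That gene was MARCKSL1 (log2 fold change 1.03, adjusted p = 0.00437), which falls outside the rule for named genes and was chosen after its values were seen. The count of 0 moved with the filter on low counts. When every gene with at least 1 count in the class was kept, edgeR called 3, 16, 3, 9, 13, 12, 16 and 2 genes in the 8 classes in the same order. Of these, 8 of the 12 genes that rose in conventional dendritic cells were interferon list members, among them IRF7, IFI44 and MX2. HLA-DRA in CD4 T cells had a log2 fold change of -0.50 in both fits. Its unadjusted edgeR p was 0.000243 with the filter and 1.5e-12 without. For IFI44 in conventional dendritic cells the fold change was 0.84 in both, with p = 9.6e-05 and 7.4e-06. The calls of HLA-DRA and IFI44 thus came with smaller p-values and not with larger changes, for a reason that was not tested. Other calls without the filter had large changes. Among them were FABP4 in CD14 monocytes (log2 fold change 7.23), BAALC in conventional dendritic cells (-3.12) and HBA2 in plasmacytoid dendritic cells (-3.00). FABP4 also leads the unnamed cluster found almost only in batch 1. In batch 3 alone edgeR called 12 genes in CD8 T cells, 4 in CD4 T cells, 2 in B cells and 0 in the other 5 classes. Leaving out 1 of the 12 patients at a time gave 0 to 9 genes in CD4 T cells, with 3 of the 12 fits above 0, and 0 to 1 genes in plasmacytoid and in conventional dendritic cells.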

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

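The tests of conventional dendritic cells against lymphocytes, of the MHC class II list between classes, within batch 3, without cells carrying markers of 2 lineages and over other splits of the samples were chosen only after the result was seen, as were 2 of the 3 forms of the test for free RNA. For the MHC class II list, the classes with the highest means (conventional dendritic and B cells) were set against those with the lowest (CD4 T cells and CD16 monocytes). The adjustment covered those pairs alone, so small adjusted p-values were partly built in by the choice. For the interferon list, conventional dendritic cells had the smallest p of the 8 classes, and the lymphocytes set against them had lower means. That adjustment too covered those comparisons alone, so its small adjusted p-values were partly built in as well.

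Conventional dendritic cells drew attention because their interferon list change exceeded that of NK cells by 0.34 ± 0.50 (SD, n = 12; 8 of 12 patients; permutation p = 0.0215, adjusted p = 0.0286), of CD8 T cells by 0.46 ± 0.51 (9 of 12; p = 0.00439, adjusted p = 0.00879) and of CD4 T cells by 0.41 ± 0.49 (11 of 12; p = 0.00244, adjusted p = 0.00879), with 0.25 ± 0.57 against B cells (adjusted p = 0.168; 0.35 and adjusted p = 0.0278 with B cells thinned, where 7 of 24 libraries had too few B cell counts to be thinned and stayed unequal). The tables argue against depth as the whole cause, since with CD4 T cells thinned to equal summed counts the difference was 0.44 ± 0.14 (SE), and against different list members, with 0.43 ± 0.14 over the 23 members tested in both classes. Cells with markers of 2 lineages stay open, since without them the differences were 0.33 ± 0.13 (SE) from CD4 T cells (10 of 12 patients, permutation p = 0.0239), 0.34 ± 0.14 from CD8 T cells and 0.22 ± 0.13 from NK cells, and none passed the adjusted test (adjusted p = 0.0742, 0.0742 and 0.140). These calls ended with a smaller mean at a similar spread, and the rule for this test was made stricter after its value was seen, so that a lost call left the explanation undecided. Within batch 3 the difference from CD4 T cells passed (0.49, exact sign-flip adjusted p = 0.0313, n = 8) and those from NK and CD8 T cells of 0.43 and 0.54 did not (exact adjusted p = 0.0833 and 0.0625), and effects of treatment and of time stay open as untested.

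In CD14 monocytes the interferon list change of 0.59 ± 0.79 may partly reflect more cells in the cluster led by interferon-induced genes. Without that cluster the change was 0.36 ± 0.15 (SE; 7 of 12 patients higher, permutation p = 0.0420), or 0.610 of its value with the cluster. That cluster is led by genes of the tested list, so a rise within cells would itself move cells into it, and taking it out cannot tell a change within cells from a change in the makeup of the class. The tables argue against cells with markers of 2 lineages as the whole cause here, since without them the change was 0.56 ± 0.23 (SE), or 0.956 of its value. An effect of treatment or of time stays open as untested.

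The MHC class II list in CD4 T cells drew attention because its change lay below that of conventional dendritic cells by 0.44 ± 0.39 (10 of 12 patients, permutation p = 0.00586, adjusted p = 0.0117; 0.43 in batch 3, exact p = 0.0313, n = 8) and below that of B cells by 0.40 ± 0.37 (11 of 12, p = 0.00195, adjusted p = 0.00781; 0.41 in batch 3, exact p = 0.00781, n = 8). Less free RNA of monocytes could give this and stays open, since the 9 measured CD14 monocyte markers changed by -0.14 ± 0.14 (SE) in CD4 T cells, a difference from the list of 0.15 ± 0.21, and for free RNA of B cells the 3 measured markers changed by 0.093 ± 0.240, a difference of 0.39 ± 0.21. Of 2 further forms on summed CPM, with the part carried by tracer genes taken off, monocytes stayed undecided in both (-0.26 ± 0.14 on the log2 scale and -78.0 ± 47.8 CPM) and both argued against B cells (-0.30 ± 0.11 and -94.6 ± 44.1 CPM), but the form written first decides, so B cells stay open too. A shift between the clusters of the class is also open, since with the shares of its 3 clusters held fixed the change over 5 members was -0.19 ± 0.05 (SE; permutation p = 0.00293), or 0.670 of the -0.29 over the whole class. These explanations cannot be told apart here, and an effect of treatment or of time stays open as untested.

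In CD16 monocytes the MHC class II change was below that of conventional dendritic cells by 0.36 ± 0.46 (9 of 11 patients, permutation p = 0.0283, adjusted p = 0.0283; 0.26 in batch 3, exact p = 0.141, n = 8). It was below that of B cells by 0.35 ± 0.44 (8 of 11 patients, permutation p = 0.0234, adjusted p = 0.0283; 0.24 in batch 3, exact p = 0.156, n = 8).

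Among the 9 samples of plasmacytoid dendritic cells before treatment, the lowest score of the cytosolic DNA sensing and inflammasome list lay apart from the nearest by 0.623 of the whole range. The highest score of the heat shock list did so by 0.5002 of the range, and the critical value for 9 samples is 0.493. Chance gives such a gap in about 1 in 20 groups, and 2 of the 22 groups tested had one, where chance gives 1.1.

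The number of genes called by edgeR was 0 in each class, so other splits of the samples say nothing about chance for these counts. All 100 of 100 splits that swapped before and after within patients, the real one included, necessarily gave as many genes. The highest counts of the other splits were 26 in plasmacytoid dendritic cells, 2 in conventional dendritic cells, 1 in CD14 monocytes, 4 in CD16 monocytes, 3 in NK cells, 3 in CD8 T cells, 1 in CD4 T cells and 3 in B cells. For genes with an unadjusted p under 0.05, the splits with as many as the real one were 90, 17, 49, 45, 20, 19, 8 and 33 of 100 in the same order, so chance could not be excluded for those numbers. The 26 genes are the highest of many splits, and whether these samples hold a structure other than the time point was not tested.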

How the results depend on the processing

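The tests in batch 3 alone, those of conventional dendritic cells against lymphocytes and those over shared list members were chosen only after the result was seen. No share passed the adjusted test in any setting run. No list did either, except with camera and a preset correlation, which called 34 combinations. In the sign-flip test 1 list alone could not pass over all combinations even at its smallest possible p. The absence of calls there does not show that no list changed. The paired fits used the patient as a block. Without the block 0 genes, 0 lists and 0 shares passed, as with it, so the calls cannot show what the block did. The number of genes with an unadjusted edgeR p under 0.05 was lower without the block in every class. It went from 489 to 19 in CD4 T cells and from 570 to 17 in CD8 T cells. Without a filter beyond 1 count edgeR called 3 genes in plasmacytoid dendritic cells, 16 in conventional dendritic cells, 3 in CD14 monocytes, 9 in CD16 monocytes, 13 in NK cells, 12 in CD8 T cells, 16 in CD4 T cells and 2 in B cells, against 0 with the filter. DESeq2's Wald test called 1 in conventional dendritic cells. In batch 3, with 8 of the 12 patients, edgeR called 12 in CD8 T cells, 4 in CD4 T cells and 2 in B cells. Leaving out 1 patient at a time gave 0 to 1 genes in plasmacytoid dendritic cells, 0 to 1 in conventional dendritic cells and 0 to 9 in CD4 T cells. Of the 3 interferon differences between conventional dendritic cells and lymphocytes that passed, 1 passed in batch 3 and 0 without cells carrying markers of 2 lineages. The cause was not tested.

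Some small differences, none past an adjusted test, reversed. In percentage points CD8 T cells were at 0.858, B cells at -0.00165 and plasma cells at -0.0903. Without cells carrying markers of 2 lineages the log2 odds were -0.11 for plasma cells and -0.072 for mixed clusters. In batch 3 they were -0.27 for plasma cells, -0.73 for platelets and -0.23 for progenitors. The interferon difference of plasmacytoid dendritic cells from CD14 monocytes was 0.039 over shared members. Leaving out 1 patient at a time, mean log2 odds ran from -0.16 to 0.27 for CD16 monocytes, -0.19 to 0.053 for CD8 T cells, -0.032 to 0.19 for B cells, -0.19 to 0.46 for plasma cells, -0.29 to 0.85 for platelets and -0.11 to 0.32 for progenitors. The interferon list in CD8 T cells ran from -0.016 to 0.073. The cause was not tested.

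The 50-cell minimum was not run for plasmacytoid and conventional dendritic cells, where under 6 patients were left. Depth limits plasmacytoid dendritic cells most by genes tested, with 2476 genes and 11 to 102 cells per sample. Single samples of other classes were small too, down to 13 cells in CD14 monocytes, 19 in conventional dendritic cells and 21 in B cells.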

Other observations

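Every gene in this part was chosen only after the values were seen. So was every test, apart from the fits without the filter on low counts and those leaving out each patient in turn. Those fits were alternatives set in advance.

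In batch 3 alone (8 patients) edgeR called 12 genes in CD8 T cells, 5 higher and 7 lower, against 0 over all 12 patients. GZMK, which encodes the granzyme of early effector and memory cells, had a log2 fold change of -0.40 (adjusted p = 0.0189), and TCF7, a transcription factor of naive and memory T cells, had -0.29 (adjusted p = 0.0223). NCR1, an activating NK receptor, had 0.71 (adjusted p = 0.0189), and LILRB1, an inhibitory receptor, had 0.47 (adjusted p = 0.0263). GZMK also leads 2 of the 5 clusters of this class. The larger, of 10110 cells, had a lower share of all cells after in 10 of 12 patients. Its mean log2 odds difference was -0.58 ± 0.69 (SD, sign-flip permutation p = 0.0117, adjusted p = 0.451). Whether the lower GZMK reflects this makeup or a change within cells was not tested.

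With every gene of at least 1 count kept, over all 12 patients, edgeR called GBP5, a guanylate-binding protein induced by interferon gamma, lower in CD8 T cells (log2 fold change -0.32, adjusted p = 0.00245) and in CD4 T cells (-0.38, adjusted p = 1.25e-05). In the same fits NK cells had MX1 called higher (0.64, adjusted p = 0.00158) and BCL2, a survival gene, lower (-0.37, adjusted p = 0.00285). With the filter MX1 had nearly the same log2 fold change there, 0.63, at an adjusted p of 0.870. The call thus rests on the smaller p of the unfiltered fit. Conventional dendritic cells had IFIT3 (1.25, adjusted p = 0.000977) and S100B (1.70, adjusted p = 7e-05) called higher. With the filter none of these was called over all 12 patients, and GBP5 in CD4 T cells was called without 1 of the 12 (log2 fold change -0.33, adjusted p = 0.0421).

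The interferon list changes of the classes went together across patients. Against the change in CD14 monocytes, Pearson's r was 0.969 for CD16 monocytes (n = 11, permutation p = 1e-05, the smallest these permutations can give, adjusted p = 7e-05; Spearman's rho 0.955, p = 2e-05), 0.912 for CD4 T cells (n = 12, p = 0.00017, adjusted p = 0.000595; rho 0.825, p = 0.00172) and 0.844 for conventional dendritic cells (n = 12, p = 0.00111, adjusted p = 0.00194; rho 0.748, p = 0.00716). For plasmacytoid dendritic cells r was 0.912 (n = 9, exact permutation p = 0.000637, adjusted p = 0.00149; rho 0.833, exact p = 0.00827). Without the 2 patients farthest from the median, r was 0.903, 0.646, 0.780 and 0.683 in these 4 classes, and within batch 3 it was 0.972, 0.894, 0.849 and 0.913. For NK, CD8 T and B cells r was 0.816, 0.763 and 0.614 (n = 12, permutation p = 0.00342, 0.00476 and 0.0304, adjusted p = 0.00479, 0.00555 and 0.0304) with rho of 0.566, 0.545 and 0.524 (p = 0.0565, 0.0720 and 0.0846). Without the same 2 patients r was 0.261, 0.237 and -0.02, so these 3 relations rest on those patients. Within batch 3 r was 0.796, 0.663 and 0.541. These 7 relations were the ones computed.

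Within CD4 T cells the MHC class II list had a mean change of -0.30 ± 0.31 in the cluster led by IL7R and LTB (11 of 12 patients lower, permutation p = 0.00977), -0.14 ± 0.28 in the cluster led by TSHZ2 and CCR7 (8 of 12 lower, p = 0.109) and 0.21 ± 0.55 in the cluster led by RTKN2 and FOXP3 (7 of 12 higher, p = 0.235). The scores covered 7, 5 and 6 list members in these clusters in the same order, so they were not all over the same genes. Differences between these clusters were not tested.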
